A study of Homo sapiens with 2 samples.

How the data were processed

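Small RNA libraries were made from BEAS-2B cells, an immortalised human bronchial epithelial line, 24 h after exposure to manganese or to vehicle. Each of the 2 groups held 1 library. Per the labels' protocols, the cells grew in a basal medium with fetal bovine serum, and total miRNA was isolated with a column kit. The dose of manganese is not given in the sources used here. The deposited count table gave whole-number counts for each mature miRNA entry, with 1 column per library, and columns were assigned to libraries by their names, which match the sample descriptions. The unit was read from the values, since the columns are whole numbers with different totals and the labels do not state it. The build was hg38 per the submitters' processing notes. The aligner, the counter, the miRNA annotation, read trimming and filters are not given in the sources used here. A second deposited table listed 1 value per entry, and in 2904 of 2904 entries this value equalled the manganese count minus the control count, with a tolerance of 0 counts.

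The count table held 2904 entries. Of these, 2565 had names starting with hsa-, and 339 had a p- prefix whose meaning is not given in the sources used here. A total of 45 entries joined several mature names in 1 row, and these were kept as single entries. No mature name occurred in more than 1 row. Counts were found for 965 entries, and 403 entries with at least 20 counts over both libraries were called measured. The measured entries took 99.9% of all counts.

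Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which gave 1.02 for the control library and 0.981 for the manganese library. The fold of an entry was the ratio of its scaled counts, manganese over control. Its 95% interval was the exact conditional binomial (Clopper-Pearson) interval of the 2 counts, computed with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Shares of a library have exact Clopper-Pearson intervals. Reads were not separated by molecular identifiers in the sources used here, so intervals and floors cover counting error only, and they include no variation between cultures. A count of 0 was set to a floor of 3 counts in that library, equal to 2.76 CPM (scaled counts) in the control and 2.80 in the manganese library, and the fold was then written as a bound. With 1 library per group there is no replicate check, and no p-value is given. Entries were counted as higher or lower by a rule of size, a fold of at least 2 in either direction with an interval that excluded 1-fold.

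The choices in this paragraph were made before the data were examined. Named miRNAs were the 10 highest and 10 lowest entries passing the rule, ranked by the interval bound nearest to 1-fold, the 5 most abundant entries, up to 4 abundant measured members of each list, and miR-21-5p, miR-210-3p, miR-7-5p, miR-34a-5p and miR-433-3p in any case. The 23 lists covered miRNA families and clusters, stress pathways, other cell types and RNA quality. For lists with at least 3 measured members, the median log2 fold minus the median of all measured entries was placed among 10000 random lists of the same size matched on mean expression over 10 bins. This percentile describes these 2 libraries and is not a test of the conditions. The interval of a list median is the order-statistic interval of its members. The alternatives were scaling by total counts, by size factors of DESeq2 1.42.0 and by totals without the 5 most abundant entries, no filter or a filter of 100 counts, rules of 1.5-fold or of an interval bound of 2-fold, an assumed replicate coefficient of variation of 20%, pseudocounts of 1 and 5, and means or summed counts in place of list medians. Results without the p- entries, and without the blood cell and 19q13 lists, were added after the data were seen. Other arms of a named hairpin, cluster or list, such as miR-126-5p, miR-145-5p, miR-194-5p, miR-17-3p, miR-18a-3p and miR-20a-5p, were named after their values were seen.

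The rule was tested on simulated data for manganese against control, in 20 runs with 200 changed entries each and a mean of 405.15 measured entries per run. Counts were drawn with Poisson error only, around the mean of the 2 libraries and with the TMM scaling taken as known. Variation between cultures and errors of scaling were not simulated, so the call rates and interval coverage describe counting error alone. The rule called 1.11% of unchanged entries, 44.9% of entries changed 2-fold and 97.0% of those changed 4-fold, with 0 in the wrong direction. The intervals covered the true fold in 95.9% of unchanged entries, 94.2% of entries changed 2-fold and 96.7% of entries changed 4-fold. Of 400 random lists of 8 members, 5.75% lay outside the range that holds the central 95% of matched lists. Hairpin positions and host genes came from a GRCh38 gene annotation, matched by the hairpin's name, and 385 of 386 measured entries with hsa- names had a hairpin gene there. Mature sequences were not used, and 344 of these entries had a single hairpin copy, while counts of the others cannot be tied to 1 locus. Plots were drawn with matplotlib 3.10.9.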

Results

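The data are mature miRNA counts from BEAS-2B cells, a human bronchial epithelial line, sampled at 24 h with vehicle or manganese. There was 1 library in each of the 2 groups. The control library held 1064179 counts over 797 entries and the manganese library 1091070 counts over 781 entries. The comparison asks how the miRNA profile of lung epithelial cells exposed to manganese, a metal that is essential in traces and toxic in excess, differs from that of unexposed cells. No difference below has a replicate check, and each one compares the 2 libraries rather than the 2 conditions.

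The manganese library held far more miR-486-5p and miR-451a, which are abundant in red blood cells, and more of the primate-specific miRNA cluster of 19q13, which is known for its expression in placenta. The count of miR-486-5p was 9597 in the control and 174822 with manganese, 18.5-fold higher (95% interval 18.1 to 18.9). Its share of all counts was 0.902% (0.884 to 0.920) in the control and 16.02% (15.95 to 16.09) with manganese. The count of miR-451a was 50 against 1564, 31.7-fold higher (23.9 to 42.9). All 5 measured members of the blood cell list and all 8 of the 19q13 list were at least 2-fold higher, while miR-19a-3p, miR-19b-3p and miR-181b-5p were among those at least 2-fold lower. Of 403 measured entries, 52 (12.9%) were at least 2-fold higher with manganese and 26 (6.45%) at least 2-fold lower. The other 325 did not pass the rule, and 239 lay within 1.5-fold of equality. Of the 52 higher entries, 13 belonged to the blood cell or 19q13 lists, and 18 to these or the other lists of foreign cell types.

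The remaining blood cell miRNAs had low counts in the control. The myeloid miR-223-3p had 4 counts in the control and 47 with manganese (11.9-fold, 4.36 to 45.6), and the haematopoietic miR-142-5p had 7 and 42 (6.09-fold, 2.71 to 16.1). The lymphoid miR-150-5p had 1 and 42 counts (42.6-fold, 7.24 to 1723). The list median was 4.29 log2 units above that of all measured entries (range of its 5 members 2.69 to 5.50), at the 99.97th percentile of matched random lists. With no filter it was 2.58 over the 9 entries with counts, where each count of 0 was set to the floor of 3. One further erythroid hairpin, MIR4732, lies beside MIR451A, and miR-4732-5p had 0 counts in the control and 67 with manganese, at least 22.7-fold higher against a floor of 3 control counts. The exact counting interval of miR-4732-5p, which covers error in both counts, started lower, at 17.9-fold. Both hairpins are in exons of a long non-coding RNA on chromosome 17 of GRCh38, MIR451A at 28861369 to 28861440 and MIR4732 at 28861655 to 28861730. The hairpin MIR486-1 is in an intron of ANK1, the erythrocyte ankyrin gene, on chromosome 8 from 41660441 to 41660508. MIR486-2 lies on the other strand from 41660444 to 41660507, so that counts of miR-486-5p belong to either.

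Higher counts in the 19q13 list came from every measured member. The list's 26 entries with counts together had 71 counts in the control and 831 with manganese, 11.9-fold higher (9.31 to 15.4). The list median, over its 8 measured entries, was 3.71 log2 units above that of all measured entries (2.82 to 5.06). It lay above each of the 10000 matched random lists. Only 8 of its 26 entries with counts were measured, some through their manganese counts alone, and with no filter the median was 2.32. The most abundant member was miR-1323, with 27 and 248 counts (9.32-fold, 6.25 to 14.4), from a hairpin on chromosome 19 at 53671968 to 53672040. The entry that joins miR-522-5p, miR-523-5p, miR-518e-5p and the 5p arms of miR-519a, miR-519b and miR-519c had 6 and 119 counts (20.1-fold, 8.98 to 55.9). For miR-512-3p the counts were 14 and 92 (6.67-fold, 3.78 to 12.7), and for miR-516b-5p 7 and 78 (11.3-fold, 5.24 to 29.04). For miR-516a-5p they were 1 and 31 (31.4-fold, 5.24 to 1282).

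Several markers of other tissues were also higher in the manganese library. The mesenchymal miR-143-3p, from a hairpin in an exon of CARMN on chromosome 5 at 149428918 to 149429023, had 26 and 354 counts (13.8-fold, 9.27 to 21.4). All 3 measured mesenchymal members passed the rule, including miR-10b-5p with 1049 and 2631 counts (2.54-fold, 2.37 to 2.74) and the joined entry of miR-199a-3p and miR-199b-3p with 25 and 76 (3.08-fold, 1.94 to 5.06). That list's median was 1.71 log2 units above all measured entries (range of its 3 members 1.43 to 3.87), at the 98.8th percentile. The mesenchymal miR-145-5p had 2 counts in each library, too few to be measured. The endothelial miR-126-3p had 19 and 39 counts (2.08-fold, 1.17 to 3.82), but miR-126-5p of the same hairpin had 11 and 8, and the fold of their sum was 1.59 (0.984 to 2.60). For muscle, miR-1-3p had 10 and 25 counts (2.54-fold, 1.18 to 5.92). The imprinted miR-483-5p, from an intron of IGF2, had 2 and 46 counts (23.3-fold, 6.10 to 198). The entry p-hsa-miR-338 had 1 and 69 counts (70.0-fold, 12.2 to 2804).

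**Figure D1:**
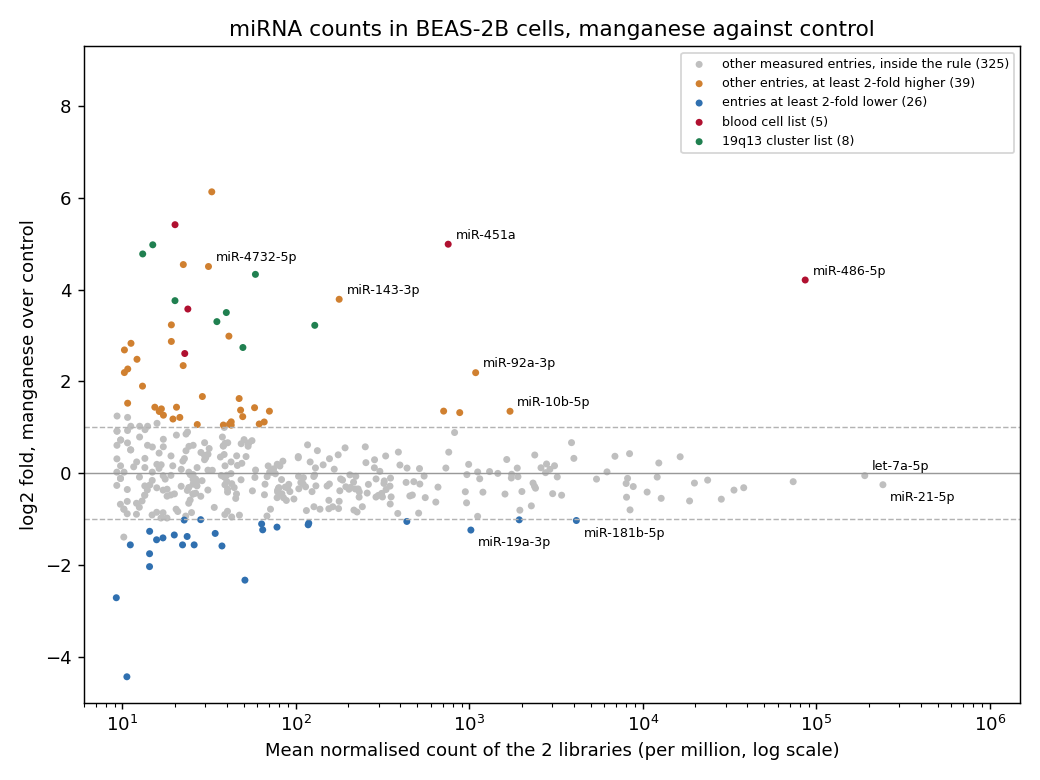
Log2 fold of manganese over control (vertical) against the mean normalised count of the 2 libraries in CPM (horizontal, log scale), 1 point per measured entry, with dashed lines at 2-fold. The 5 blood cell and 8 19q13 entries all lie above the upper line, and miR-4732-5p is drawn at its bound.

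Among the miRNAs at least 2-fold lower, miR-181b-5p had the highest counts, 6025 in the control and 2902 with manganese (2.05-fold lower, 1.96 to 2.14). The arms miR-19a-3p and miR-19b-3p belong to the growth-promoting miR-17~92 cluster of chromosome 13, the latter also to an X-linked copy. The count of miR-19a-3p was 1554 in the control and 648 with manganese, 2.36-fold lower (2.16 to 2.59), and that of miR-19b-3p was 2813 against 1369, 2.03-fold lower (1.90 to 2.16). The ciliated-cell and p53-linked miR-34b-5p had 61 and 20 counts (3.01-fold lower, 1.79 to 5.26). Other miRNAs passing the rule were miR-4286 with 638 and 303 counts (2.08-fold lower, 1.81 to 2.39) and miR-3613-5p with 175 and 79 (2.18-fold lower, 1.66 to 2.89). The Xq27 miR-513c-5p had 25 and 6 counts (4.11-fold lower, 1.64 to 12.2). The entry p-hsa-miR-293 had 92 and 18 (5.04-fold lower, 3.02 to 8.88), and miR-99a-3p had 22 and 1 (21.7-fold lower, 3.51 to 895). For miR-2682-3p the counts were 20 and 0, at least 6.57-fold lower against a floor of 3 manganese counts. Its exact counting interval, which covers error in both counts, started at 4.87-fold lower. The hairpin MIR19A is in an exon of MIR17HG on chromosome 13 at 91350891 to 91350972. The arms miR-19b-3p and miR-181b-5p each have 2 hairpin copies, whose counts cannot be separated.

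Scaling mattered more for the lower than for the higher set. When the 5 most abundant entries were left out of the library totals, the median log2 fold of all measured entries moved from −0.08 to 0.10, a shift of 0.19, and the split became 60 higher and 15 lower. The folds of miR-19b-3p, miR-181b-5p, miR-4286 and miR-3613-5p were then 0.562, 0.556, 0.548 and 0.521, short of the rule, while miR-19a-3p still passed at 0.481. With at least 100 counts over both libraries, 17 entries were higher and 10 lower.

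Stress-linked lists fixed in advance showed small shifts in both directions. Of 7 measured p53-linked members, 1 was lower by the rule, miR-34b-5p, and 0 were higher, and the median was −0.47 log2 units from all measured entries (−1.50 to 1.08), at the 2.32nd percentile. The 4 members below the median of all entries were the arms of the miR-34b/c cluster, which also belong to the multiciliated-cell list, among them miR-34c-5p with 1591 and 816 counts (1.92-fold lower, 1.77 to 2.09). The other 3 lay above it, with miR-192-5p at 626 and 1139 (1.85-fold higher, 1.67 to 2.04) and miR-194-5p at 28 and 55 (1.99-fold higher, 1.24 to 3.26). For miR-34a-5p, a direct p53 target, the counts were 326 and 330, a fold of 1.03 (0.879 to 1.20) whose side of 1 depended on the scaling. Of 7 hypoxia-linked members 2 were higher, miR-210-5p and the mesenchymal miR-199a-3p entry (median 0.28, 91.7th percentile), and the hypoxia-inducible miR-210-3p had 356 and 482 counts (1.37-fold, 1.20 to 1.58). Of 15 members linked to NRF2, the master regulator of antioxidant genes, 1 was higher, the blood cell miR-142-5p, with a median of −0.10 and a mean of 0.11. Of 13 NF-kB and inflammation members 2 were lower, miR-181b-5p and miR-212-3p. That list's median was 0.10 (78.3rd percentile), but the fold of its summed counts was 0.817 (0.813 to 0.821). Most of that sum was miR-21-5p, with 285179 and 235815 counts, and the abundant miR-221-3p had 36676 and 24381 counts (1.48-fold lower, 1.46 to 1.51). Of 6 members linked to the unfolded protein response 1 was higher, the mesenchymal miR-199a-3p entry. That list's median was 0.37, but the fold of its summed counts was 0.691, since miR-30c-5p had 16427 and 11060 counts (a fold of 0.683, with an interval that excluded 1-fold). Of the manganese-linked miRNAs of neuronal studies, miR-137 had 38 and 29 counts and miR-7-1-3p had 79 and 79, neither passing the rule. Counts of miR-433-3p were 2 and 0, too few for a fold, and miR-7-5p was listed at 0 in both libraries.

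The medians of the epithelial and multiciliated-cell lists both lay inside the central 95% of their matched random lists. The miR-200 family, which maintains epithelial identity, had 3 measured members. Their median was 1.15 log2 units above all measured entries (member range 0.74 to 1.31), at the 93.0th percentile. The counts were 32 and 74 for miR-200b-3p (2.35-fold, 1.53 to 3.67), 29 and 60 for miR-429 (2.10-fold, 1.33 to 3.39) and 45 and 70 for miR-200a-3p (1.58-fold, 1.07 to 2.35). The multiciliated-cell list had 5 measured members, 1 of them lower by the rule. Its median was −0.60 (member range −1.50 to −0.47), at the 3.54th percentile. Its MIR34B and MIR34C hairpins on chromosome 11, from 111512938 to 111513515, gave 1825 and 950 counts in all, a fold of 0.528 (0.488 to 0.571).

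Most large families lay close to the median of all entries, and members named here for passing the rule were chosen after their values were seen. The let-7 family, a set of growth-restraining miRNAs, had a median of −0.13 (29.9th percentile), with 1 of 19 members lower, let-7e-3p. The miR-17~92 and paralogue list had a median of −0.03 and a mean of 0.21, with 3 of 14 members higher, miR-92a-3p, miR-18a-3p and miR-106b-3p, and 2 lower, miR-19a-3p and miR-19b-3p. The medians were −0.15 for the miR-29 family (1 of 6 lower, miR-29c-5p, but 0.069 with at least 100 counts), −0.06 for the miR-30 family (1 of 10 higher, miR-30d-3p, mean 0.06) and −0.30 for the family of miR-15 and miR-16 (0 of 10 passing). They were −0.20 for the miR-232724 clusters (0 of 8 passing), −0.22 for the miR-221 and miR-222 cluster (0 of 4 passing) and 0.17 for the miR-183, miR-96 and miR-182 cluster (1 of 3 higher, miR-96-5p with 4 and 22 counts). The imprinted 14q32 cluster had a median of −0.01 and a mean of 0.06, with 2 of 30 members higher, miR-432-5p and miR-495-3p. Of 12 measured entries that overlap other RNA classes, used as a sign of RNA quality, 2 were higher, miR-4508 and miR-4497, and 0 lower, with a median of 0.49 (−0.19 to 1.03) at the 88.3rd percentile, and −0.13 with at least 100 counts. Of the 20 lists with a median, 3 lay above the central 95% of their matched random lists, those of blood cells, 19q13 and mesenchymal cells, and only the p53-linked list, with its 4 arms of the miR-34b/c cluster, lay below it. The p53-linked value depended on the filter and summary, at −0.20 with no filter, −0.13 with at least 100 counts, −0.17 as a mean and −0.077 from summed counts. A single list of independently drawn entries would lie outside the central range in about 5% of cases. Arms of 1 hairpin or cluster may not be independent, so this rate need not hold for lists such as 19q13 or the p53-linked one.

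**Figure D2:**
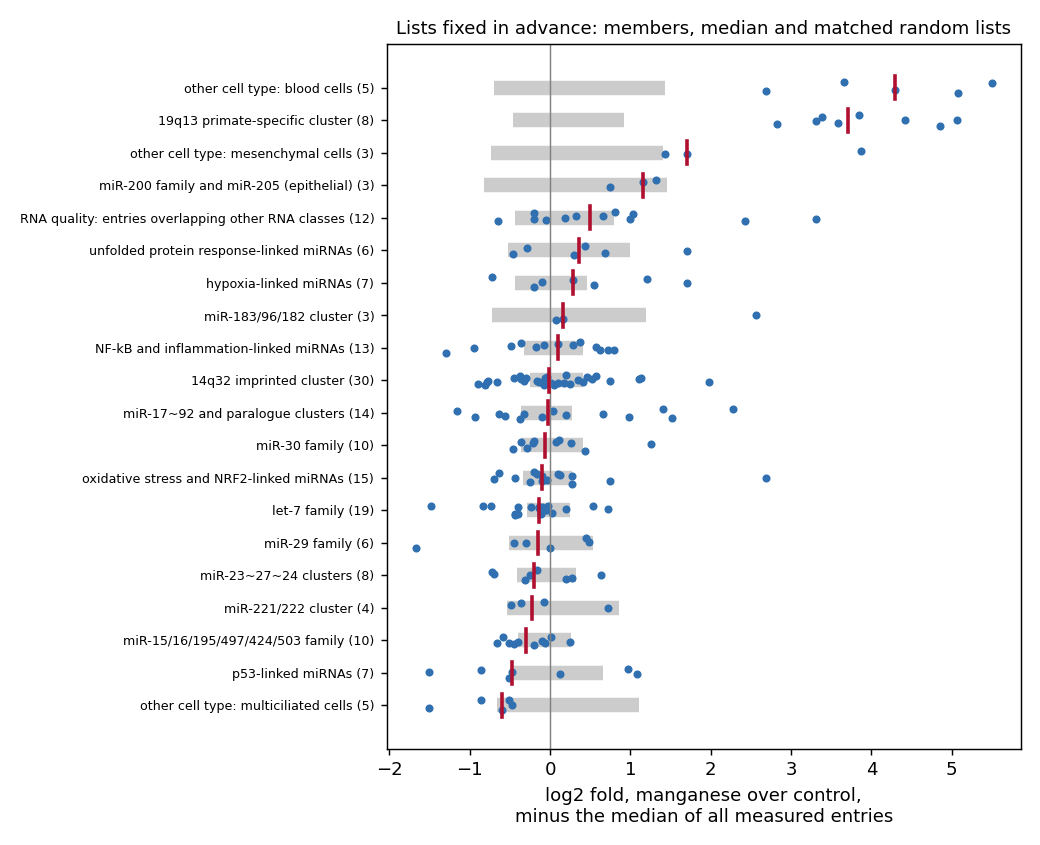
Log2 fold of manganese over control minus the median of all measured entries, for the members (points) and median (red line) of each list fixed in advance, with grey bars over the central 95% of matched random lists and measured members in brackets. The blood cell, 19q13 and mesenchymal medians, at 4.29, 3.71 and 1.71, lie right of their grey bars.

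Within the miR-17~92 cluster the arms went apart. Its last member, miR-92a-3p, which was chosen for naming after its values were seen, was at 391 CPM in the control and 1781 CPM with manganese, 4.56-fold higher (4.10 to 5.08). That arm is made from the hairpin MIR92A1 on chromosome 13 at 91351314 to 91351391 and from an X-linked copy, MIR92A2. Of the 6 measured arms made only from the chromosome 13 cluster, 3 lay below the median of all entries, among them miR-20a-5p with 1275 and 802 counts (a fold of 0.638, 0.583 to 0.698). The rarer miR-18a-3p had 12 and 32 counts (2.71-fold higher, 1.36 to 5.77) and miR-17-3p 18 and 33 (1.86-fold higher, 1.02 to 3.51). The arm miR-17-5p had only 3 and 10 counts, too few to be measured. In the paralogue cluster of chromosome 7, miR-93-5p had 3066 and 1842 counts (1.64-fold lower, 1.55 to 1.74), while miR-25-3p had 2692 and 2876 (1.08-fold higher, 1.03 to 1.14).

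**Figure D3:**
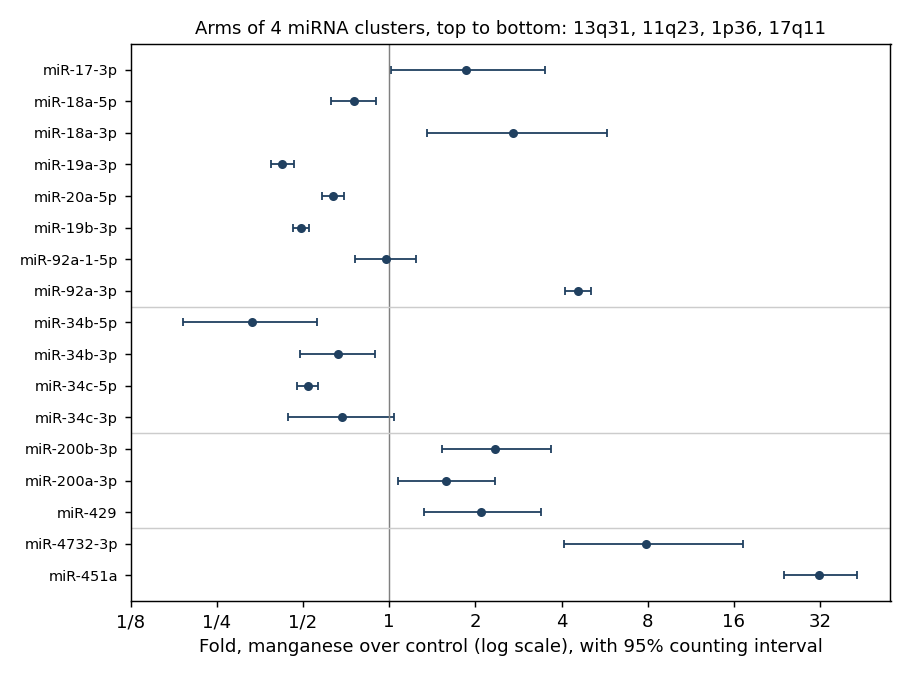
Fold of manganese over control on a log scale, with 95% counting intervals, for arms of the miR-17~92 cluster (13q31), the miR-34b/c cluster (11q23), the miR-200b cluster (1p36) and the miR-451a cluster (17q11). Point estimates of all 4 miR-34 arms lie below 1-fold, while miR-92a-3p lies at 4.56 and miR-19a-3p of the same cluster at 0.423.

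The most abundant miRNA in both libraries was miR-21-5p, an oncogenic miRNA made from an exon of VMP1 on chromosome 17. It had 285179 counts in the control and 235815 with manganese, and its share was 26.8% (26.7 to 26.9) and 21.6% (21.5 to 21.7). A share also falls when another entry takes more, and that of miR-486-5p went from 0.902% to 16.02%. The next most abundant, let-7a-5p, had 210027 and 199234 counts, a fold of 0.962 (0.956 to 0.968) whose side of 1 depended on the scaling. The counts of let-7f-5p were 84857 and 73471 (1.14-fold lower, 1.13 to 1.15), and those of let-7b-5p were 45882 and 36259 (1.25-fold lower, 1.23 to 1.27). When the 5 most abundant entries were left out of the totals, the log2 fold of miR-21-5p shrank from −0.253 to −0.068. Those of let-7f-5p and let-7b-5p shrank to −0.0013 and −0.133. In the authors' deposited table of count differences, 172 measured entries were positive, 223 negative and 8 zero. The authors' deposited table gave miR-486-5p a difference of 165225, which is 86.1% of the positive sum, and miR-21-5p a difference of −49364. The unscaled difference and the scaled fold had opposite directions for 1 measured entry, miR-92b-3p, with 2969 and 2946 counts.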

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

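The results without the p- entries, and without the blood cell and 19q13 lists, were chosen only after the data were seen. No miRNA or list past its threshold reversed direction in the alternatives run. Of the 403 measured entries, 60 changed sides of 1-fold over the 4 scalings. Some list medians short of a threshold changed sign, such as the unfolded protein response list, 0.37 against −0.45 from summed counts. Leaving the 5 most abundant entries out of the totals gave 15 lower entries in place of 26. With no count filter 82 entries were higher in place of 52, and with at least 100 counts 17 were higher and 10 lower, since fewer entries enter. When the interval bound itself had to reach 2-fold, 26 were higher and 4 lower, and a rule of 1.5-fold gave 57 lower. With no filter the list medians were 2.32 for 19q13 and 2.58 for blood cells, still above all measured entries. Scaling by total counts gave 4 entries whose unscaled difference and fold had opposite directions, in place of 1. The cause of these shifts was not tested beyond the construction of each alternative. Total counts, DESeq2 size factors and an assumed coefficient of variation of 20% kept both counts within 1.5 times. Leaving out p- entries, or the blood cell and 19q13 lists, only dropped rows from the calls without new scaling. Those counts were thus fixed by the calls already made and are no check of them. Without the blood cell and 19q13 lists, 39 were higher and 26 lower. Counting every row separately moved nothing, since no name was repeated. For the 84 miRNAs the rule names, 368 of 420 alternative values stayed inside the counting interval and 52 moved outside it. For the lists, 94 of 96 alternative values stayed inside the order-statistic interval of the members. Depth limits the low entries most, through wider counting intervals.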

Other observations

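The HOX-embedded and Xq27 sets, and all tests below except that of blood-abundant miRNAs, were chosen only after the result was seen. Of miRNAs encoded within the HOX gene clusters, miR-10a-5p had 3255 and 5082 counts (1.58-fold, 1.52 to 1.66), miR-10b-5p 1049 and 2631 (2.54-fold, 2.37 to 2.74) and miR-196b-5p 43 and 108 (2.55-fold, 1.77 to 3.72). The counts of miR-196a-5p were 29 and 35 (1.22-fold, 0.727 to 2.08), and miR-10a-3p passed the rule as lower with 27 and 10 (a fold of 0.376, 0.162 to 0.801). The miR-506 to miR-514 cluster of Xq27, best known from testis, had 168 and 76 counts over 11 entries, 2.18-fold lower (1.65 to 2.90). Within it, miR-508-3p had 53 and 21 counts and miR-509-3p had 31 and 12.

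Arms of 1 hairpin did not always go together. Of 81 hairpins with both arms measured, 28 had both intervals off 1-fold, and 8 of those had arms in opposite directions. The arms of MIR106B were at folds of 0.729 (5p) and 2.49 (3p), and those of MIR10A at 1.58 (5p) and 0.376 (3p). Some arms were listed at 0 in both libraries beside a counted partner, such as miR-423-5p beside miR-423-3p with 141 and 132 counts. An entry at 0 can therefore not be read as an absent miRNA, which also bears on the bounds given for miR-4732-5p and miR-2682-3p.

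Blood cell and 19q13 miRNAs were higher together in the manganese library. All 13 measured members passed the 2-fold rule, although the count filter favours such entries. With no filter the list medians were 2.58 and 2.32 in place of 4.29 and 3.71. There each count of 0 was set to the floor of 3, which hides the fold of rare entries. The fall in these medians therefore does not measure the filter's effect. Over all 26 of the 19q13 entries with counts, the summed counts were 71 and 831. Scaling, or the share taken by miR-486-5p, is argued against only over the 4 scalings run, where the lowest fold of any member was 5.85. The size ratios of these scalings, manganese over control, spanned only 0.867 to 1.03, so a fall below 2 was out of reach. RNA or reads from blood or another outside source may have entered the manganese library. Only blood as a source was tested, on 16 other measured miRNAs abundant in blood, chosen before their values were seen. Their median was 0.077 log2 units above all measured entries (−0.26 to 0.33), at the 88.2nd percentile, with 0 passing the rule. Most are expressed by these cells too, with a median control count of 258, so small outside additions to their own counts stay hidden. An outside source would also have to supply miR-486-5p, whose share of all counts went from 0.902% to 16.02%. The test does not decide on blood, and it has no bearing on other outside sources, including any source of the 19q13 miRNAs. Its rule counted against blood only if the whole interval of the median lay below 0. A mere lack of increase could therefore not count against blood. Raised transcription of these loci by manganese could also give 13 of 13 members higher, and with 1 library per group it cannot be told apart from an outside source.

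The higher count of miR-92a-3p beside lower counts of the abundant miR-19a-3p and miR-20a-5p of its cluster is a separate pattern, in which the rarer miR-18a-3p and miR-17-3p were higher too. More output of the MIR92A1 hairpin stays open: its other arm, miR-92a-1-5p, had a fold of 0.971 (0.761 to 1.24), but arms of 1 hairpin can differ, and 2 of the 81 hairpins had arms farther apart. More miR-92a-3p might come from the X-linked copy, but the arms made only by that cluster had 0 counts in the control and 2 with manganese, too few to decide, and several of them are listed at 0 in both libraries. The outside source of the first pattern might also bring miR-92a-3p, which is abundant in red blood cells. The 11 blood-abundant miRNAs with a control count no higher than its own had a median of 0.17 (−0.26 to 0.73), which bears only on blood. Such a source stays open, as does an effect of manganese on the processing or stability of this arm, which was not tested.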
